A study of Mus musculus with 622 samples.

How the data were processed

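The data are RNA sequencing profiles of 622 single cells from the pancreatic islets of wild-type C57BL/6 mice, with 1 library per cell. Per the labels' protocols, cells were captured on a C1 Integrated Fluidic Circuit, cDNA was made with the SMARTer Ultra Low RNA kit, and libraries were built with Nextera XT. The authors deposited a single table of RPKM values, reads per kilobase of gene scaled to the mapped reads of the cell, with 44448 genes named by Entrez gene ID and 1 column per cell. The submitters' processing notes list CASAVA 1.8.2, FastQC and the mouse build GRCm38 (mm10). The aligner, the read counter and the annotation are not given in the sources used here. Gene symbols and positions came from the RefSeq table for the same build, which matched 39725 IDs. The other 4723 IDs held a median of 0.11% of a cell's RPKM. In all, 12162 genes were at 0 in every cell, and RPKM summed to between 433550 and 1437837 per cell.

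The number format of the table parted the columns into 359 at full precision and 263 rounded to 4 decimals. The labels do not mention this split, and whether it marks separate runs or separate processing is not known. It was treated as a technical set of columns, and values were recomputed within each set. Depth is not in the table, so whole reads were recovered from ratios of RPKM values between cells, which are ratios of whole numbers once gene length and depth are divided out. A unit of 1 read was found for 22951 of the 23143 genes present in at least 5 full-precision cells. Of the values under 100 reads, 2063332 in the full-precision and 1165911 in the rounded columns, 100.0% were whole within a tolerance of 0.05. The units were chosen to make full-precision values whole, so only the rounded columns, where depth alone was fitted, are a check on them. Gene lengths of 7 mitochondrial genes set the absolute scale. The recovered reads made up a median of 99.7% (range 64.9% to 100.0%) of each cell's depth. On simulated data, 2741 of 3000 genes were solved and 100.0% of their counts were right. Recovered reads served for depth and for thinning only. Thinning drew 250000 reads from each cell with at least that many, and 8 cells with fewer were left out of thinned values. All comparisons used RPKM as deposited, with no count model, since RPKM is not a count.

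The cell filter, the hormone rule, the markers, the lists and the rule for named genes were chosen before the data were examined. A cell passed with at least 1000 genes at 1 RPKM or more. Hormones were Ins1 plus Ins2, Gcg, Sst, Ppy and Ghrl, and a cell was multi-hormone when the second of them held at least 10% of their sum. Multi-hormone cells were the doublet candidates. They took part in clustering and were left out of class shares and comparisons. No other doublet score was used. Cells were clustered on log2(RPKM + 1) of 95 cell type markers, by Ward linkage on Euclidean distances into 15 clusters, and 2 further marker symbols had no match in the table. Clusters were named by a rule whose thresholds were set after the data were seen. A cluster took the name of a class outside the endocrine ones when that class's markers had a mean z score of at least 2 and at least 3 of them were detected in 50% or more of its cells. Otherwise it took the endocrine class of the hormone that led most of its cells, if that class's markers also scored highest of the endocrine classes and at least 3 were detected. Markers of a class outside the endocrine ones scored higher, below that threshold, in 3 named clusters: the PP-like one (glial 1.06 against 0.90) and 2 beta-like ones (ductal 0.36 against 0.23, glial 0.23 against 0.15). All others stayed unnamed. A class of fewer than 5 cells was not compared.

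Since the labels name no animal or chip, cells are not replicates, and no p-value, standard error or count of changed genes was computed. Shares carry exact Clopper-Pearson intervals at 95%, and a count of 0 is given the upper limit of 3 counts of the total. These intervals and limits cover counting error only. Alpha-like, delta-like and PP-like cells were each compared with beta-like cells by log2((class mean + 1) / (class mean + 1)) of RPKM. Where a class was listed at 0 no ratio is printed. Markers, which defined the clusters, entered no comparison or list, and their values are given as description only. Named genes were the 10 highest and 10 lowest ratios among genes outside the marker list with a class mean of at least 20 RPKM and 1 RPKM or more in at least 50% of the cells of the higher class. From each list the text names members with the largest ratios in each direction and a mean of at least 5 RPKM in either class. For cell-to-cell spread, the 10 largest coefficients of variation were named among genes outside the marker list with a mean of at least 100 RPKM in beta-like cells that reached 1 RPKM in at least 50% of them. On simulated changes in beta-like cells, 100 genes raised 8-fold gave a median log2 ratio of 2.94 with 97.0% within 1 of the true value, and 100 genes raised 2-fold gave 0.92 with 93.0%.

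The 17 lists covered glucose entry and KATP coupling, glycolysis, the TCA cycle, the respiratory chain, genes normally kept low in beta cells, pan-endocrine transcription factors, secretory granules, exocytosis, receptors and ion channels. They also covered ER chaperones, immediate early genes, antioxidant genes, proliferation, genes uneven among beta cells, major histocompatibility class I genes and sex-linked genes. Members with a mean of at least 1 RPKM in either class entered, without the markers. The list's median log2 ratio was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression, and a list stood apart outside the central 95% of them. In the self-test, a list of 20 genes raised 8-fold came to percentile 100.0 and a list of 20 unchanged genes to 79.8. Lists of acute-phase and neutrophil genes were added after the data were seen and are used in the closing section only.

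Alternatives fixed in advance were other gene minimums, detection at 0.1 RPKM, other hormone thresholds, multi-hormone cells kept in, other pseudocounts and other numbers of clusters. They also included clustering on the 2000 most variable genes (Leiden on 15 neighbours of 30 principal components), class medians, rescaling without the hormones, other level filters and leaving out each cell of a class of 10 or fewer. Added after the data were seen were each column set alone, the mitochondria-rich insulin cluster counted as beta-like, clusters led by more markers of another class left unnamed and, for the lists, beta-like cells matched to alpha-like cells in genes detected at 250000 reads (3 for each, within its column set). Ratios without the highest cell of a small class were also added then. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9. No column of the table was left out. A few genes that meet the rules for named genes are not reported here.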

Results

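RNA was measured in 622 single cells from the pancreatic islets of wild-type C57BL/6 mice. Each cell was captured on a Fluidigm C1 chip, a microfluidic device that lyses cells and amplifies their cDNA in separate chambers, and gave its own library. The labels put all cells in 1 group and name no animal, chip or condition. All cells therefore counted as 1 sample, with no replicate error, and the values below are class means, medians, quartiles and shares of cells. Reads assigned to genes had a median of 1119226 per cell and ran from 2461 to 6111747. A median of 5200 genes per cell reached 1 RPKM (reads scaled by gene length and by the mapped reads of the cell). The columns of the table fell into 2 technical sets by number format, 359 written at full precision and 263 rounded to 4 decimals. These sets also differed in depth, with medians of 811202 and 1607347 reads, and in detected genes, with medians of 5754 and 4124. With each cell thinned to 250000 reads, the medians were 5930 and 4197 genes with at least 1 read, so values from each set, or their range, stand beside the main pooled shares and most named-gene ratios. Ratios of list members are pooled, with both sets given where their signs differ.

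In most cells the RNA of a single islet hormone led by far, and insulin led most often. Of the 622 cells, 593 had at least 1000 genes at 1 RPKM, a share of 95.3% (95% exact Clopper-Pearson interval 93.4 to 96.9). Of these 593 cells, 126 held a second hormone at 10% or more of their summed hormone RNA, a share of 21.2% (18.0 to 24.8). The share was 22.6% in the full-precision columns and 19.4% in the rounded columns. With the second hormone at 25 percent, the multi-hormone share was 12.0%. Insulin with glucagon was the most frequent combination, in 64 cells, followed by somatostatin with insulin in 19, pancreatic polypeptide with insulin in 18 and pancreatic polypeptide with somatostatin in 16. Glucagon was combined with pancreatic polypeptide in 8 cells and with somatostatin in 1. Multi-hormone cells, treated as candidate doublets, were left out of every comparison between cell classes. Those with pancreatic polypeptide and somatostatin had a median of 3614.5 genes at 1 RPKM, against 5918 to 6076 in the combinations with insulin. Whether each multi-hormone cell is a doublet was not tested. Intervals cover counting error only, since amplified reads are not independent molecules and the cells are not replicates.

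The remaining 467 cells contained the 4 main endocrine classes of the islet, together with cells from clusters that held markers of immune or connective tissue cells. Beta-like cells, named from clusters led by insulin, numbered 318, or 68.1% (63.7 to 72.3). This share was 74.1% (68.4 to 79.3) in the full-precision columns and 60.3% (53.2 to 67.1) in the rounded columns. Glucagon-led alpha-like cells numbered 31, or 6.64% (4.55 to 9.29), with 6.08% and 7.35% in the column sets. There were 12 somatostatin-led delta-like cells, or 2.57% (1.33 to 4.45), with 1.90% and 3.43%. The 10 PP-like cells, led by pancreatic polypeptide, made up 2.14% (1.03 to 3.90), with 1.90% and 2.45%. In the delta-like cluster, 15 of 27 cells were multi-hormone and were left out. The delta-like share was 4.55% with multi-hormone cells kept in, and clustering on the most variable genes named neither a delta-like nor a PP-like class. Immune-like cells numbered 12, or 2.57% (1.33 to 4.45), with 1.14% and 4.41% in the column sets. Stellate or fibroblast-like cells numbered 6, or 1.28% (0.47 to 2.78), with 1.90% and 0.49%. No cluster could be named for 78 cells, or 16.7% (13.4 to 20.4), with 12.9% and 21.6% in the column sets. Of the unnamed cells, 39 formed an insulin-led cluster with a median of 25.3% of RPKM in mitochondrial genes, against 11.1% in beta-like cells. The others came from insulin-led clusters whose alpha, delta or PP markers scored above their beta markers. Multi-hormone cells made up 12 of 25, 49 of 52, 14 of 20 and 21 of 38 cells of these clusters. Whether their remaining cells are mixtures below the 10% threshold was not tested. No epsilon-like class was found, and the ghrelin gene Ghrl reached 1 RPKM in 9 of 593 cells, at most at 6.32 RPKM.

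Hormone transcripts defined the endocrine classes, so they are given as description. Mean Ins2 (chromosome 7, 142678656 to 142679726, GRCm38) was 334719 RPKM in beta-like cells and 1212 in alpha-like, 1154 in delta-like and 1048 in PP-like cells. Within beta-like cells, mean Ins2 was 257871 RPKM in the full-precision and 456551 in the rounded columns. Mean Gcg (chromosome 2, 62474530 to 62483653) was 273786 RPKM in alpha-like cells and 97.4 in beta-like cells. Mean Sst (chromosome 16, 23889573 to 23891342) was 132875 RPKM in delta-like and 133 in beta-like cells. Mean Ppy (chromosome 11, 102099931 to 102101319) was 450986 RPKM in PP-like and 137 in beta-like cells. Pyy, which encodes peptide YY, had means of 76826 RPKM in PP-like, 57513 in delta-like and 11306 in alpha-like cells, against 59.2 in beta-like cells. Iapp, which encodes islet amyloid polypeptide, had means of 65082 RPKM in beta-like and 37550 in delta-like cells. The transcription factor Mafa, a marker of mature beta cells, was hardly detected, with 1 RPKM or more in 5 of 318 beta-like cells and a mean of 0.061. Whether reads that map to several places or the gene models used lowered this value was not tested, so it is not a measure of Mafa expression. Among markers of other cell types, the keratin gene Krt7 reached 1 RPKM in 301 of the 318 beta-like cells, with a mean of 96.4 RPKM.

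**Figure D1:**
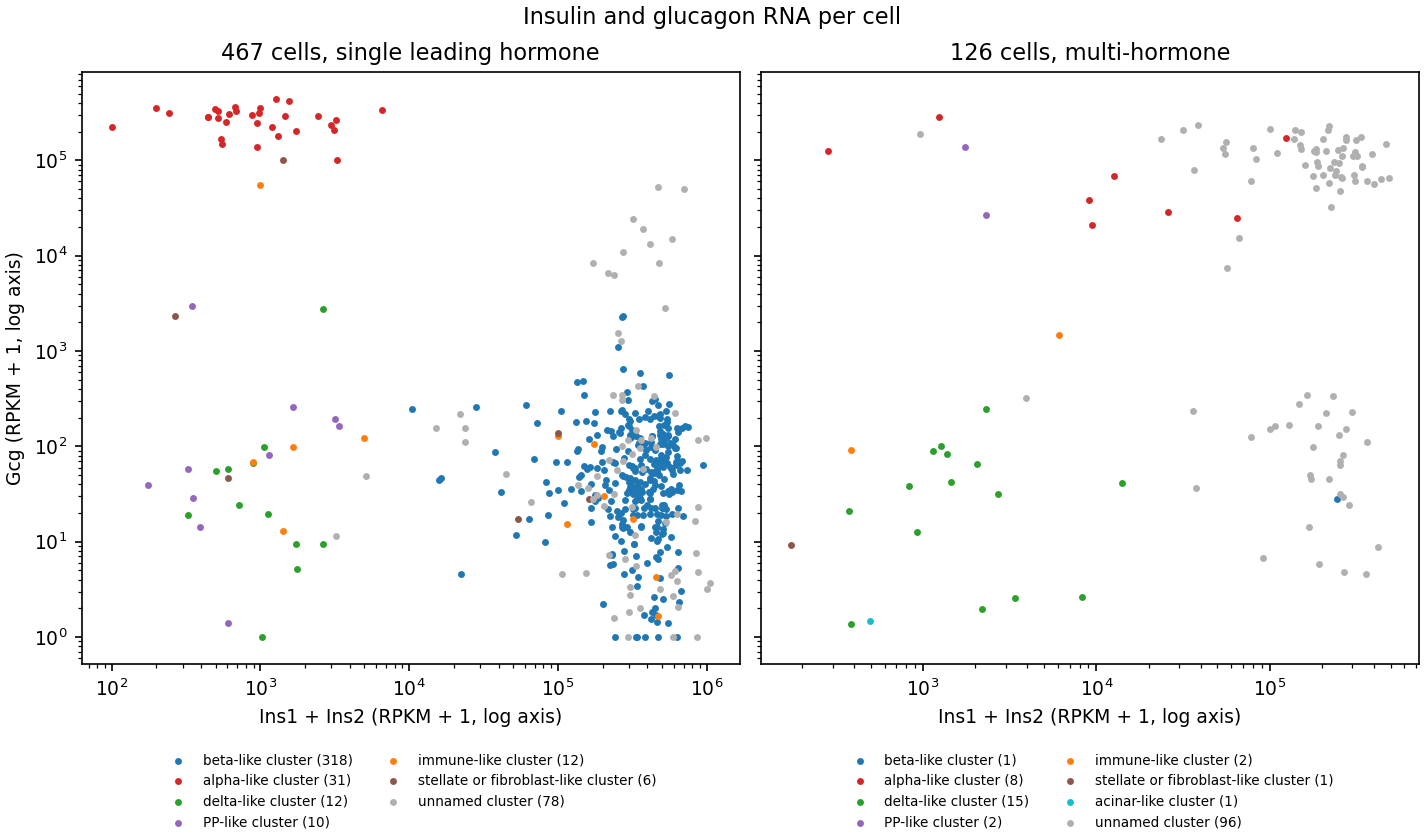
Insulin (Ins1 plus Ins2, horizontal) and glucagon (Gcg, vertical) RNA of the 593 passing cells, in RPKM + 1 on log axes; each point is 1 cell, coloured by the name of its cluster. The left panel holds the 467 cells with a single leading hormone, with 318 beta-like cells at the lower right and 31 alpha-like cells at the upper left, and the right panel holds the 126 multi-hormone cells.

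Alpha-like and beta-like cells differed in many genes besides the hormones that defined them. Alpha-like cells held more RNA of genes for amino acid transport (Slc38a5), selenium-dependent peroxide removal (Gpx3), a mitochondrial hypoxia-inducible protein (Higd1a) and a kinase that inhibits pyruvate dehydrogenase (Pdk4). Beta-like cells held more RNA of the proinsulin convertase Pcsk1, the granule protein gene Sytl4, the prolactin receptor Prlr and the little-studied Fam151a. Gpx3 (chromosome 11, 54902854 to 54910387) had a mean of 1350 RPKM in the 31 alpha-like cells and 21.8 in the 318 beta-like cells, with medians of 1134 and 0.773. Pcsk1 (chromosome 13, 75089420 to 75134861) had a mean of 0.388 RPKM in alpha-like and 138 in beta-like cells and reached 1 RPKM in 3 of 31 and 310 of 318 cells.

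Of the 10 named genes higher in alpha-like cells, Slc38a5 (chromosome X, 8271381 to 8280179) had the largest ratio, with a log2 ratio of class means of 6.10 (4.82 in the full-precision and 6.61 in the rounded columns). Its RNA was uneven, with 16 of 31 alpha-like cells at 1 RPKM or more and quartiles of 0 and 79.6 RPKM. Gpx3 followed at 5.89 (6.59 and 5.07), and all 31 alpha-like cells held it. In the full-precision columns alone, the ratio of Gpx3 was the largest of the 10. Higd1a stood at 5.76 and was at 1 RPKM in 30 of 31 alpha-like and 7 of 318 beta-like cells. Pdk4 (chromosome 6, 5483351 to 5496278) stood at 5.24 and was at 1 RPKM in 27 of 31 alpha-like cells and 0 of 318 beta-like cells, which allows a share of up to 0.94%. The others were the pseudogene Gm9790 at 5.65, the endothelin gene Edn3 at 5.07, the acid-sensitive potassium channel gene Kcnk3 at 5.01, the ubiquitin ligase adaptor gene Klhl13 at 4.95, the kinase gene Wnk3 at 4.58 and the calcium-binding protein gene Rcn3 at 4.55. Whether the reads of Gm9790 came from a gene of like sequence was not tested. Single cells weighed on some of these means. The highest alpha-like cell held 506 RPKM of Pdk4, beside a mean of 37.5, and 376 RPKM of Wnk3, beside a mean of 31.4. Over the 10 genes the log2 ratios ran from 4.57 to 6.59 in the full-precision columns and from 4.19 to 6.61 in the rounded columns. The median size of the 20 ratios in alpha-like against beta-like cells was 5.66, and 2.87 with a pseudocount of 10 in place of 1.

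The 10 named genes lower in alpha-like cells were led by Fam151a (chromosome 4, 106733915 to 106748292), with a log2 ratio of -6.72 and 1 RPKM or more in 0 of 31 alpha-like cells, which allows a share of up to 9.68%, and 282 of 318 beta-like cells. Pcsk1 followed at -6.64 (-6.57 in the full-precision and -6.68 in the rounded columns). The long non-coding RNA gene B830017H08Rik, at -6.31, and the carbonic anhydrase gene Car15, at -5.67, lie 257 bases apart on chromosome 16. The serine protease gene Prss53 stood at -6.29 and Cox6a2, a subunit gene of cytochrome c oxidase, at -6.13. Sytl4, whose product binds Rab27a on secretory granules, stood at -5.99, and Fkbp1b, whose product binds ryanodine receptors, at -5.36. Prlr and Frzb, which encodes a secreted Wnt antagonist, both stood at -5.30. The ratios ran from -6.81 to -4.99 in the full-precision and from -6.68 to -4.52 in the rounded columns. Of the 20 genes, Kcnk3, Wnk3, Fam151a, Prss53 and Cox6a2 overlap another annotated gene, so their reads cannot be assigned to them with certainty.

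**Figure D2:**
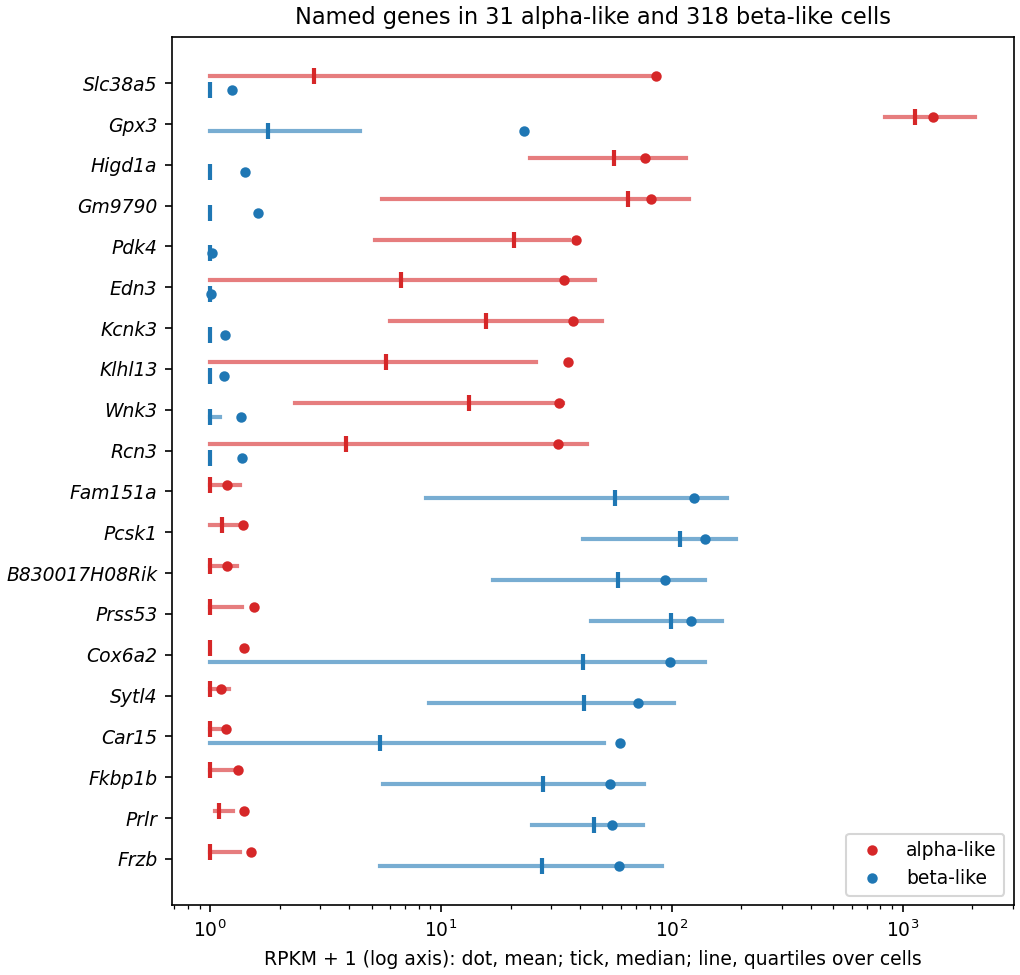
The 20 named genes in 31 alpha-like (red) and 318 beta-like (blue) cells, as RPKM + 1 on a log axis; dots are class means, ticks medians and lines the quartiles over cells. The upper 10 genes have higher means in alpha-like cells, up to 1350 RPKM for Gpx3, and the lower 10 have higher means in beta-like cells, up to 138 RPKM for Pcsk1.

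Groups of genes with shared functions also differed between alpha-like and beta-like cells. Of 17 gene lists, 7 stood apart from random lists matched in size and mean expression, 6 of them lower and 1 higher in alpha-like cells. Percentiles among 10000 random lists describe these cells and are not p-values. The median of all 12357 genes compared was -0.25, so list medians are read against that level. Alpha-like cells also had fewer detected genes, with a median of 4537 at 250000 reads against 5484 in beta-like cells. Against 90 beta-like cells matched in this number (median 4628), chosen after the data were seen, 6 of the 17 lists stood apart. Genes of the unfolded protein response and ER chaperones, which fold and clear secretory proteins, were among the lists with the lowest percentile, with a median log2 ratio of -1.38 (percentile 0.00, and 0.00 in each column set). Of its 24 members, 23 were lower in alpha-like cells. Sdf2l1 had means of 2.32 RPKM in alpha-like and 59.0 in beta-like cells, Wfs1 0.696 and 29.3, Edem1 2.04 and 20.1, and Pdia4 12.6 and 66.8. Trib3 was listed at 0 in alpha-like cells and had a mean of 9.05 RPKM in beta-like cells.

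Of the energy metabolism lists, those of glycolysis and the TCA cycle were lower in alpha-like cells. The glycolysis list had a median log2 ratio of -1.05 over 13 members (percentile 0.38), 12 of them below 0, at percentile 0.20 in the full-precision columns and, where it no longer stood apart, 6.65 in the rounded columns. With the matched beta-like cells the list glycolysis was at -0.73 (percentile 2.59) and no longer stood apart. Its largest ratios were those of Ldha at -2.65, of Pfkm at -2.14, of Pgk1 at -1.53 and of Pkm at -1.52. Ldha, a gene normally low in beta cells, reached 1 RPKM in 8 of 318 beta-like cells and stood at -3.19 in the full-precision and -0.01 in the rounded columns. Gapdh, another member, had low means of 6.63 RPKM in alpha-like and 8.41 in beta-like cells, and whether reads that map to several places or the gene models used lowered them was not tested. The TCA cycle list had a median of -0.73 over 18 members (percentile 0.59, and 0.18 and 0.33 in the column sets), with 15 below 0. Fumarate hydratase Fh1 stood at -2.02, Dlst at -1.98 and Mdh1 at -1.33, while the succinate dehydrogenase subunit Sdhd stood at 0.42. The list of ATP synthase and respiratory chain genes did not stand apart, with a median of -0.15 over 22 members (percentile 38.6), Cyc1 at -2.03, Ndufa10 at -1.11 and Atp5d at 0.98. Alpha-like cells had 15.4% of their RPKM in mitochondrial genes (median), against 11.1% in beta-like cells. This share was 89.7% in cells that did not pass the filter. Whether cell quality, the share of RPKM held by hormones or metabolism underlies the difference was not tested.

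Receptors for hormones and nutrients had a median log2 ratio of -1.12 over 31 members (percentile 0.04, with 8.28 in the full-precision and 0.00 in the rounded columns), and 20 members were below 0. Lower in alpha-like cells were Prlr, the GLP-1 receptor Glp1r at -3.88 and the glucagon receptor Gcgr at -3.69, and the galanin receptor Galr1 was listed at 0 there. Higher in alpha-like cells were the vasopressin receptor Avpr1b at 3.59, the fatty acid receptor Ffar4 at 3.41, the glutamate receptor subunit Gria2 at 3.16 and the lipid receptor Gpr119 at 2.43. Avpr1b had a mean of 11.1 RPKM in alpha-like and 0.0046 in beta-like cells. Genes described as uneven among beta cells had a median of -1.84 over 12 members (percentile 0.00, with 0.00 and 0.76 in the column sets). Among them Npy stood at -4.66, Gad1 at -4.53, Spock2 at -3.82 and Th at -3.61, while Cd9 stood at 1.55 and Cd81 at 1.31. The ratio of Npy leaned on few beta-like cells, with 16 of 318 at 1 RPKM, a mean of 25.7 RPKM and a highest cell of 5015 RPKM. The proliferation list had a median of -1.27 over 17 members (percentile 0.11, with 0.53 and 0.23), with Pcna at -1.54 and Tyms at 1.02 (1.86 and -0.86 in the column sets). Genes normally kept low in beta cells had a median of 1.06 over 7 members (percentile 99.7, and 99.1 in the full-precision columns), with Mgst1 at 3.59 and Igfbp4 at 2.63. In the rounded columns Mgst1 stood at 0.10 and Igfbp4 at 0.02, and only 2 members passed the level filter. This list's median was -0.01 with no filter on low values, and the call for the receptor list ended in the full-precision columns alone. With class medians in place of class means, the calls for the receptor list, the proliferation list and the genes uneven among beta cells ended as well, and 3 of 17 lists stood apart.

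The other 10 lists did not stand apart, although single members differed. In the glucose entry and KATP coupling list (12 members, median 0.08 with -0.19 in the full-precision and 0.29 in the rounded columns, percentile 80.9), the pyruvate carboxylase gene Pcx stood at -1.20, Kcnh6 at 0.81 and the KATP channel subunit Kcnj11 at 0.76. Among pan-endocrine transcription factors (22 members, median 0.18 with -0.54 and 0.44 in the column sets, percentile 93.1 with 25.7 and 96.7), the carbohydrate response factor Mlxipl stood at -4.03, Tshz1 at -1.73 and Isl1 at 0.93. In the secretory granule list (18 members, median -0.18, percentile 37.1), Pcsk1 and Sytl4 were joined by Scg2 at -2.23 and Chgb at -1.63, against Gnas at 2.47, Pcsk1n at 1.62 and Resp18 at 1.52. Exocytosis genes had a median of -0.44 over 17 members (percentile 16.1), with Napa at -1.03, Syt4 at -0.95 and Syt11 at 0.42. Ion channels beyond the KATP list (17 members, median -0.24 with -0.47 and 0.07 in the column sets, percentile 46.7) held the gap junction gene Gjd2 at -3.29 and Lrrc8a at -1.31, against Kcnk3 and Scn3a, the latter at 1.41 (-0.21 and 2.93 in the column sets).

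Stress-related lists went in no common direction. Immediate early and dissociation stress genes had a median of -0.05 over 22 members (-0.33 and 0.24 in the column sets, percentile 67.1), with Ier3 at -2.85 and Nr4a1 at -1.05 against Atf3 at 2.94 and Myc at 2.74. Antioxidant genes had a median of -0.24 over 19 members (percentile 28.0), with the heme oxygenase gene Hmox1 at -3.04 and the metallothionein gene Mt2 at -2.53 against Gpx3 and the mitochondrial peroxiredoxin gene Prdx3 at 1.60. The major histocompatibility class I and interferon response list had a median of -0.65 over 10 members (-0.76 and 0.04 in the column sets, percentile 7.71), with B2m at -1.28, Tapbp at -0.98 and Psmb8 at 0.83 (-0.61 and 1.93 in the column sets). The sex-linked list had a median of 0.38 over 4 members (-0.03 and 0.75 in the column sets, percentile 86.6), with Uty at -0.77, Eif2s3y at 0.70 and Ddx3y at 0.38.

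**Figure D3:**
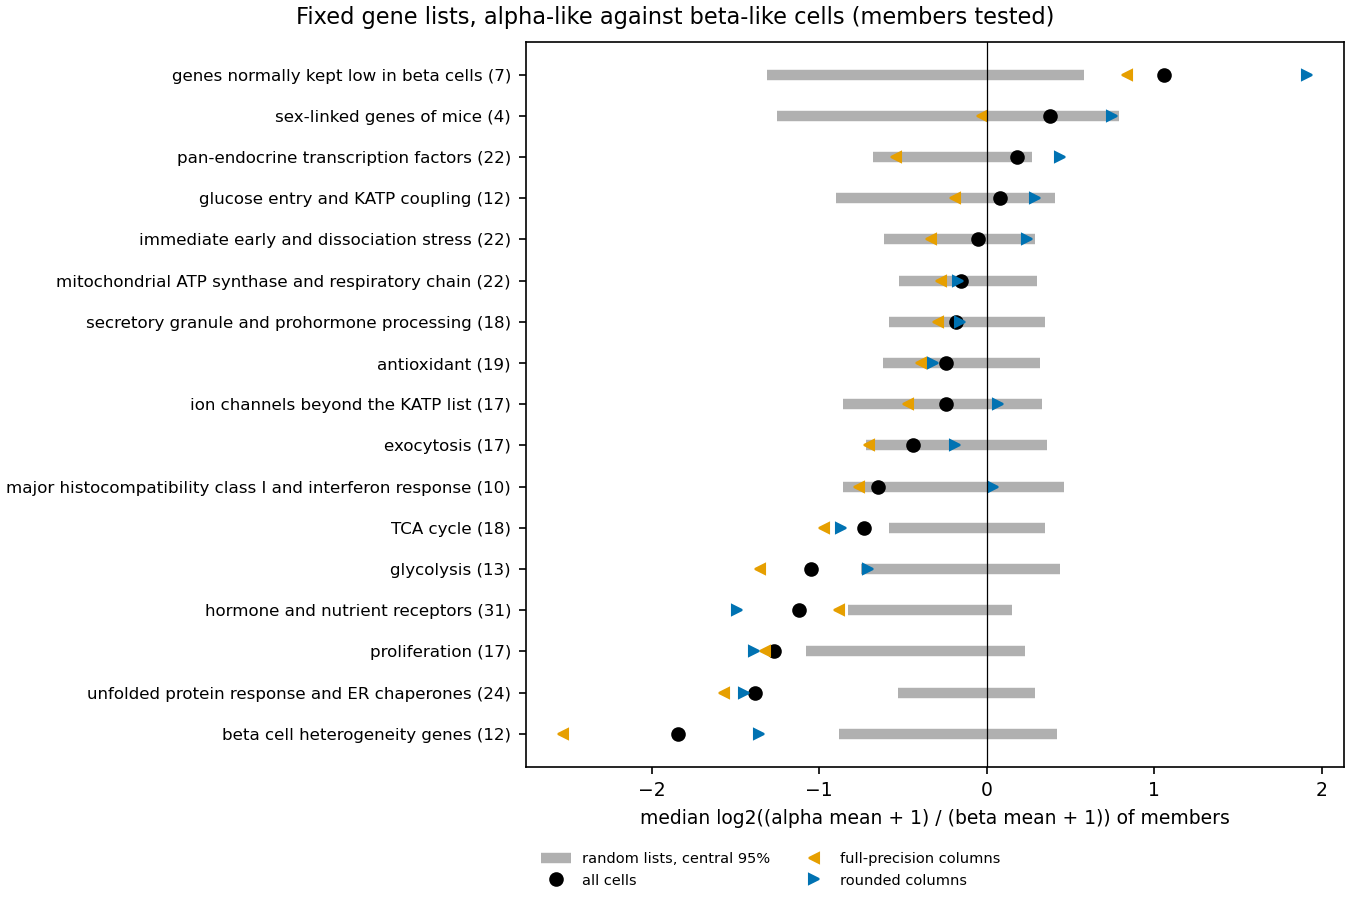
Median log2 ratio of alpha-like to beta-like class means for the 17 gene lists, members compared in brackets; black dots are all cells, coloured triangles the full-precision and rounded columns, and grey bars the central 95% of random lists. The list of ER chaperones lies at -1.38, left of its grey bar, and the list of genes normally kept low in beta cells at 1.06, right of its grey bar.

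Delta-like cells differed from beta-like cells in genes for arginine breakdown, tetraspanins and a calcium-binding protein, among others. Arginase 1, encoded by Arg1 (chromosome 10, 24915207 to 24927470), had a mean of 716 RPKM in the 12 delta-like cells and 2.33 in the 318 beta-like cells, a log2 ratio of 7.75 (7.94 in the full-precision and 7.98 in the rounded columns). Adh1 (chromosome 3, 138277585 to 138290698), an alcohol dehydrogenase gene, had means of 0.053 and 155 RPKM, a log2 ratio of -7.21, and was at 1 RPKM in 0 of 12 delta-like cells, which allows a share of up to 25.0%, and 255 of 318 beta-like cells.

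The other named genes higher in delta-like cells, with log2 ratios in the full-precision and the rounded columns in brackets, were Tspan12 at 7.33 (7.41 and 7.35), Gpx3 at 6.44 (7.32 and 5.53), the surface glycoprotein gene Cd24a at 6.01 (5.36 and 8.34), the imprinted gene Mest at 5.79 (6.37 and 5.16), the ephrin gene Efnb3 at 5.61 (4.26 and 6.13), Tspan8 at 5.13 (6.09 and 3.91), Klhdc8b at 5.06 (4.45 and 5.83), the calbindin gene Calb1 at 5.02 (5.08 and 4.55) and the bicarbonate transporter gene Slc4a4 at 4.92 (0.26 and 5.90). Tspan12 was uneven, with a median of 2.58 RPKM beside its mean of 185. The ratio of Slc4a4 rested on the rounded columns. Without the highest of the 12 cells it was 3.50, as that cell held 66.6% of the summed RPKM, and the ratio was 4.24 for Calb1, 4.31 for Klhdc8b, 4.98 for Mest and 6.41 for Tspan12. Lower in delta-like cells were Prss53 at -6.73 (-6.67 and -6.84), the kinetochore gene Spc25 at -6.55 (-6.32 and -6.85), Ociad2 at -6.51 (-6.66 and -6.37), the aromatic amino acid decarboxylase gene Ddc at -6.49 (-6.91 and -6.17), the sulfate donor synthase gene Papss2 at -6.41 (-5.85 and -7.01), Cox6a2 at -6.40 (-6.05 and -6.75) and the stress-response gene Nupr1 at -6.21 (-8.05 and -4.98). Fam151a and Dapl1 were listed at 0 in all delta-like cells and had means of 124 and 83.0 RPKM in beta-like cells. Among the 10 genes lower in delta-like cells, 5 overlap another annotated gene, as do 4 of the 10 higher ones. With 12 cells in the class, of which 5 had full-precision columns, a single cell weighs heavily on each mean. The median size of the 20 ratios in delta-like against beta-like cells was 6.40, and 3.71 with a pseudocount of 10.

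PP-like cells shared some of these differences from beta-like cells. The complement factor I gene Cfi (chromosome 3, 129836727 to 129875332) had a mean of 131 RPKM in the 10 PP-like cells and 0.291 in beta-like cells, a log2 ratio of 6.68 (6.73 in the full-precision and 6.76 in the rounded columns). Papss2 (chromosome 19, 32595669 to 32667187) had means of 0.187 and 193 RPKM, a log2 ratio of -7.35, and was at 1 RPKM in 0 of 10 PP-like cells, which allows a share of up to 30.0%, and 317 of 318 beta-like cells.

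Also higher in PP-like cells, with the same values in brackets, were Tspan12 at 6.30 (5.01 and 7.12), Tspan8 at 5.99 (5.54 and 6.15), Olfm3 at 5.23 (0.51 and 6.19), Gpx3 at 4.89 (5.38 and 4.35), the inositol phosphatase gene Ocrl at 4.61 (4.00 and 5.07), Kcnk3 at 4.39 (5.09 and 2.77), Calb1 at 4.29 (4.81 and 3.85) and Iqschfp at 4.26 (1.75 and 5.48). Olfm3 and Iqschfp rested mainly on the rounded columns. Several of these ratios leaned on a single cell. Without the highest of the 10 cells, which held 74.4% of the summed RPKM of Kcnk3, its ratio was 2.71, and the ratio was 3.06 for Iqschfp, 3.56 for Calb1, 3.89 for Ocrl, 3.90 for Olfm3, 4.16 for Gpx3, 5.34 for Tspan12 and 6.07 for Cfi. Lower in PP-like cells were Nupr1 at -7.14 (-8.10 and -6.02), Fam151a at -6.71 (-7.16 and -6.11), Prss53 at -6.66 (-6.53 and -6.83), the monoamine oxidase gene Maob at -6.65 (-6.78 and -6.52), Spc25 at -6.61 (-6.64 and -6.70), Pcsk1 at -6.40 (-7.06 and -5.81), the phosphatase inhibitor gene Ppp1r1a at -5.99 (-6.21 and -5.90) and Sytl4 at -5.79 (-5.37 and -6.29). Cox6a2 was listed at 0 in PP-like cells. Another annotated gene overlaps 4 of the 10 higher and 4 of the 10 lower genes, Cfi, Papss2 and Iqschfp among them. Of the named genes in the comparisons of alpha-like, delta-like and PP-like cells with beta-like cells, Gpx3 was higher in all 3, and Cox6a2, Fam151a and Prss53 were lower in all 3. Since the same beta-like cells served each comparison, these overlaps are not independent. The median size of the 20 ratios in PP-like against beta-like cells was 6.35, and 3.63 with a pseudocount of 10.

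Among beta-like cells, Tm2d2, Sat1 and the stress-response gene Nupr1 varied most over all cells of the abundant genes outside the marker list. The rank of Tm2d2 leaned on a single cell. Over 484 such genes, with a mean of at least 100 RPKM, the coefficient of variation over 318 cells had a median of 0.91 (quartiles 0.79 and 1.07). The median spread of genes among beta-like cells was 1.39 with a mean of at least 20 RPKM. Tm2d2 had the largest value, 3.27, which rested on the rounded columns (4.73) more than on the full-precision columns (1.46). Its highest cell, of the rounded columns, held 5414 RPKM, beside an upper quartile of 113 RPKM over all beta-like cells. In the full-precision columns Nupr1, Bnip3, Mt2, Sat1 and B2m, given below, all had larger values than Tm2d2. The polyamine enzyme gene Sat1 followed at 2.47 (1.83 in the full-precision and 4.01 in the rounded columns) and Nupr1 at 2.32 (2.17 and 2.44 in the column sets). Nupr1 was at or near 0 in many cells, with quartiles of 0 and 361 RPKM. The metallothionein gene Mt2 stood at 2.24 (1.95 and 2.99), the mitophagy gene Bnip3 at 1.98 (2.00 and 1.66), Sem1 at 1.91 (0.685 and 2.33), B2m at 1.73 (1.60 and 1.75), Snrpd2 at 1.71 (1.08 and 2.04) and Acot13 at 1.71 (1.25 and 2.45). The value of Sem1 also leaned on a single cell, which held 6214 RPKM beside an upper quartile of 255 RPKM. As description only, since these markers served to define the cells, Iapp stood at 0.36, Ins2 at 0.44 and Ins1 at 0.51, while the hormones of other classes stood at 5.57 for Ppy, 2.13 for Gcg and 1.83 for Sst. Of the genes described as uneven among beta cells, neuropeptide Y (Npy) reached 1 RPKM in 16 of 318 cells, or 5.0% (2.9 to 8.0), and tyrosine hydroxylase (Th) in 73, or 23.0% (18.4 to 28.0). Glutamate decarboxylase (Gad1) reached it in 167 cells, or 52.5% (46.9 to 58.1), and Cd81 in 185, or 58.2% (52.5 to 63.7). All 4 shares were higher in the full-precision than in the rounded columns. They were 6.2% and 3.3% for Npy, 28.7% and 13.8% for Th, 57.4% and 44.7% for Gad1, and 68.2% and 42.3% for Cd81. Cell-to-cell spread holds technical and biological variation together, and these data hold no replicate that would part them.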

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

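All tests in this part were chosen after the results they concern were seen, except the test of a beta cell captured with the immune cell.

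Cells left out of every comparison held RNA of markers of other cell types. Prss2, Dcn and Lyz2 were among the markers that named these clusters, so their values are description only. The 1 acinar-like cell, which was also multi-hormone, had 81906 RPKM of the trypsinogen gene Prss2, against at most 140 in any beta-like cell. The stellate or fibroblast-like cells had a median of 278 RPKM of the decorin gene Dcn, against at most 0.887 in beta-like cells. The immune-like cells had a median of 3589 RPKM of the lysozyme gene Lyz2, against at most 198 in beta-like cells. The 29 cells that did not pass the filter had a median of 2902 RPKM of Ins2, with a median of 417 genes at 1 RPKM and 89.7% of RPKM in mitochondrial genes.

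The first pattern is insulin and glucagon RNA together in 64 cells, of which 2, both in the immune-like cluster, held no more insulin than the highest alpha-like cell (6574 RPKM) and no more Gcg than the highest beta-like cell (2307 RPKM). Free RNA of the hormones alone, from other cells, is argued against for the 64 cells as a set. It is not argued against for these 2, nor for each other cell, since 52 of the 64 held both gene sets below. The 10 named alpha-like genes outside the hormones stood at a median of 47.84% of their alpha-like mean (49.2% without the 2 cells), beside 39.5% for Gcg. The 10 named beta-like genes stood at 54.8%, beside 56.0% for Ins2. Free RNA with all transcripts of lysed cells would raise these genes too, so the values cannot tell it from a captured cell. A pair of cells captured together is consistent with the data, as 81.2% of these cells (52 of 64, interval 69.5 to 89.9, and 83.9% without the 2 cells) held at least 5 genes of both sets, which were chosen in other cells, the alpha-like and beta-like ones. Single cells that make both hormones stay open and cannot be told apart from pairs here: their median of 6145 genes at 250000 reads, beside 5484 in beta-like and 4537 in alpha-like cells, is what pairs could give, but no value excludes single cells with many genes. No biological explanation beyond this was tested.

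The second pattern is RNA of acute-phase genes in beta-like cells of the full-precision columns, where Lcn2 reached 1 RPKM in 48 of 195 cells, or 24.6% (18.7 to 31.3), against 0 of 123 cells in the rounded columns, which allows a share of up to 2.44%. Neutrophil RNA is argued against, since the number of these cells with S100a8, an abundant neutrophil transcript, was 0 of 195, which allows a share of up to 1.54%. Fewer reads in the rounded columns are argued against as well. Their beta-like cells had a median of 1692815 reads, against 809706 in the full-precision columns. With cells thinned to the same number of reads, however, the rounded beta-like cells had fewer genes, 4322.5 against 5800. Lower detection of genes in the rounded columns therefore stays open, since read depth does not measure it, and it was not tested for these genes. Genes left out of the rounded columns by the processing stay open and cannot be told apart from a difference between the cells: of 12 acute-phase genes, 1 was above 0 in at least 10 rounded cells (C3, in 10 cells, with Cfb in 9), and 6 were at 0 in all of them, of which Hp and Orm1 bear no weight, being above 0 in 0 and 2 of the 359 full-precision cells. The labels name no animal, chip or run, so no biological explanation was tested.

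The third pattern is insulin RNA in the 12 immune-like cells, with a median Ins2 of 94751 RPKM. Ins2 medians in other non-beta cells were 870 RPKM in alpha-like, 945 in delta-like and 435 in PP-like cells. Free insulin RNA at this level stays open for 5 of the 12 immune-like cells, between 824 and 4112 RPKM. The others held 88532 to 437770 RPKM, above every alpha-like (up to 6053), delta-like (up to 2518) and PP-like cell (up to 3134). Cells with much insulin had been left out of those classes as multi-hormone, however. The 6 stellate or fibroblast-like cells had a median of 24270, with insulin at 54336 to 161773 RPKM in 3. For the others, free insulin RNA therefore stays open too and cannot be told apart from captured beta cells. A beta cell captured with the immune cell is compatible with the values of the 12 cells as a set. The 10 named beta-like genes stood at a median of 24.95% of their beta-like mean (range over genes 8.16% to 54.5%), beside 42.2% for Ins2. The cells were unlike, however. The 5 cells with Ins2 of 824 to 4112 held 0 to 2 of these genes at 1 RPKM, which argues against a captured beta cell for them. The other cells held 3 to 10, and a captured beta cell stays open for single ones among them. The cell with the highest Ins2, 437770 RPKM, held 3 of these 10 genes at 1 RPKM with Pcsk1 listed at 0. A cell with 88532 RPKM of Ins2 held 4, with 784 RPKM of Iapp. Uptake of beta cell material by immune cells was not tested, and no biological explanation was tested.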

How the results depend on the processing

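Each column set alone, the mitochondria-rich insulin cluster counted as beta-like, clusters led by more markers of another class left unnamed and, for the lists, beta-like cells matched in detected genes were alternatives chosen after seeing the data, and the others were fixed in advance. All 20 named genes of the alpha-like, delta-like and PP-like comparisons kept their direction in each alternative run for them: pseudocounts on class means, class medians, rescaling, 2000 genes, the second hormone at 5 percent, multi-hormone cells kept in, and those chosen after seeing the data. The named genes were picked for the largest ratios in these same cells, so a kept direction says little. Clustering alternatives were run for the shares alone. The cause of the changes below was not tested, except where fewer cells or genes entered by construction. The share of cells passing the cell filter was 97.27% at 500 genes, 93.25% at 2000 genes and 98.87% with detection at 0.1 RPKM. The multi-hormone share was 26.14% with the second hormone at 5 percent and 11.97% at 25 percent. The beta-like share of 68.1% became 74.00% at 500 genes and 75.55% at 2000 genes, 61.11% with the second hormone at 25 percent, 53.79% with multi-hormone cells kept in, 72.38% and 74.52% with pseudocounts of 0.1 and 10 for clustering, and 56.96% with clustering on the 2000 most variable genes. It was 60.17% with clusters led by more markers of another class left unnamed, 76.45% with the mitochondria-rich insulin cluster counted as beta-like, 74.14% in full-precision columns only and 60.29% in rounded columns only. The delta-like share was 4.55% with multi-hormone cells kept in. Clustering on the most variable genes named no such class, with a delta-like share of 0 and a PP-like share of 0. The median size of the 20 named ratios, 5.66 for alpha-like against beta-like cells, was 7.38 with a pseudocount of 0.1, 2.87 with 10 and 6.47 with RPKM rescaled without the hormones. For delta-like against beta-like cells it went from 6.40 to 7.92 with 0.1 and 3.71 with 10, and for PP-like against beta-like cells from 6.35 to 7.89 and 3.63. Without each PP-like cell in turn (leave-one-out) it ran from 6.10 to 6.45; the other classes have more than 10 cells and had no such run. Single genes moved more, as Kcnk3 did from 4.39 to 2.71 without its highest PP-like cell. Of gene lists in alpha-like against beta-like cells, 3 in place of 7 stood apart with class medians, where the median of all genes moved from -0.25 to -0.65, and 6 with beta-like cells matched in detected genes, where it was -0.11. The median of the list genes normally kept low in beta cells, 1.06, changed sign to -0.01 (percentile 86.16) with no filter on low values. It had too few members for a value with class medians, in rounded columns only and with a mean of at least 10 RPKM, and the sex-linked list had too few in the last of these. With class medians the percentile of the list hormone and nutrient receptors was 12.04, that of the list proliferation 16.92 and that of the list beta cell heterogeneity genes 20.37. The receptor list also no longer stood apart with multi-hormone cells kept in (4.77), in full-precision columns only (8.28) and with no filter on low values (6.97), nor the proliferation list with a mean of at least 10 RPKM (21.8), nor the list glycolysis in rounded columns only (6.65) or with beta-like cells matched in detected genes (2.59). The median spread of genes among beta-like cells was 1.39 with a mean of at least 20 RPKM. Of the values of single genes and lists under the alternatives, 719 stayed within their limits, 165 moved beyond them, in 9 cases a list no longer stood apart, and 1 value, given above, changed sign in a list that had stood apart. Lists that did not stand apart were not counted when their sign changed. Depth limits genes near 1 RPKM, and classes of 10 or 12 cells limit the delta-like and PP-like means.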

Other observations

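The count of mitotic beta-like cells, the sex-linked shares and the look at immune and connective tissue genes were chosen after the data were seen, and no test of an explanation was run on them.

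The immune and connective tissue genes below were markers that defined the clusters, so their values are description only. In the 12 immune-like cells mean Lyz2 was 4185 RPKM, Tyrobp, which encodes a signalling adaptor of myeloid cells, 3129 RPKM and the complement gene C1qb 1577 RPKM, against 1.12, 0.606 and 0.065 in beta-like cells. The T cell receptor component gene Cd3e was at 1 RPKM in 0 of 593 cells, which allows a share of up to 0.51%. The 6 stellate or fibroblast-like cells had means of 486 RPKM for Dcn and 451 for the collagen gene Col1a2, with Dcn at 0 in 2 of them. They also held hormone RNA, with insulin at 161773, 100406 and 54336 RPKM in 3 cells, Gcg at 101919 in 1 and Ppy at 158805 in 1. The endothelial gene Emcn had a mean of 405 RPKM there, but it reached 1 RPKM in 4 of 593 cells, 2 of them beta-like, so this mean rests on at most 2 cells. Other endothelial markers were higher there too, with means of 94.1 RPKM for Egfl7, 73.8 for Kdr and 31.1 for Cdh5. In beta-like cells these means were 0.459, 0.091 and 0.178 RPKM. The name of the class may therefore not hold for all 6 cells. The secreted phosphoprotein gene Spp1 had a mean of 8607 RPKM there and 117 in beta-like cells. Of the beta-like cells, 4 of 318, or 1.26% (0.34 to 3.19), held at least 4 of 6 mitotic genes at 1 RPKM.

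Combinations of hormones were not spread evenly over the leading hormones. Pairs of cells with the same hormone go uncounted and stay in their class, so random pairing would also give higher shares for rarer hormones. Whether pairing accounts for the shares below was not tested. A second hormone at 10% was present in 76 of 486 insulin-led cells, or 15.6% (12.5 to 19.2), in 22 of 55 Gcg-led cells, or 40.0% (27.0 to 54.1), in 14 of 27 Sst-led cells, or 51.9% (31.9 to 71.3), and in 14 of 25 Ppy-led cells, or 56.0% (34.9 to 75.6). Cells with insulin and glucagon numbered 2.06 for each alpha-like cell, those with insulin and somatostatin 1.58 for each delta-like cell and those with insulin and pancreatic polypeptide 1.8 for each PP-like cell. At least 3 hormones reached 10% in 14 cells.

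Y-linked RNA was found in most cells. At least 1 of Ddx3y, Eif2s3y, Kdm5d and Uty reached 1 RPKM in 522 of 593 cells, or 88.0% (85.1 to 90.5), and Xist in 5 cells, at most at 6.38 RPKM, each with a Y-linked gene. Of the acute-phase list, Saa3 reached 1 RPKM in 15 and C3 in 25 of the 195 full-precision beta-like cells, against 0 of 123 rounded ones (up to 2.44%) for Saa3 and 5 for C3. Of 13 neutrophil genes, none reached 1 RPKM in more than 3 of the 195 cells. In all, 17 of 17086 genes present in at least 5% of full-precision cells were at 0 in every rounded cell.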
